A study of Mus musculus with 17 samples.

How the data were processed

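Liver RNA of 17 mice was sequenced and 1 library was made per mouse as far as the sample labels say. Nothing beyond the labels states that the libraries of a group came from separate animals, so p-values measure only the spread between these samples, which may be technical. RNA libraries were made with a stranded total RNA kit and sequenced from both ends, per the labels' protocols. Reads were handled with bcl2fastq 2.17.1.14, TopHat2 2.0.9, Cufflinks 2.2.1 and Cuffdiff on the genome build GRCm38 p5, per the submitters' processing notes. The gene annotation and the version of Cuffdiff were not given in the sources used here.

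The deposited table holds 1 value per gene and library, read here as FPKM (fragments scaled to transcript length and to the mapped fragments of the library), which the authors made with the Cufflinks tools. The unit was inferred from the tools named and from the range of the values, since no header names it. No read counts were used here, so the sequencing depth of each library is unknown and no counting interval can be given. The summed FPKM ranged from 466883 in Het APAP 3 to 916006 in OE APAP 300, and 10631 to 11496 genes reached 1 FPKM per library. The 10 most abundant genes held 18.2% to 28.8% of a library's FPKM. The table lists 46073 genes, of which 45139 gene IDs had a symbol and 934 had none, and 13810 were at 0 in every library. No column belonged to an unmatched sample. No pair of libraries was a duplicate, the smallest median absolute log2 difference between libraries being 0.135.

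Some abundant genes were listed at exactly 0 in every library of a genotype and treatment and were high elsewhere, among them Trf, Hpx, Fga, Fgb, mt-Co1 and mt-Co3. These zeros were treated as failed estimates. A gene was left out where it was at 0 throughout a genotype and drug block and had at least 10 FPKM elsewhere (89 genes), or where it lay within 100 kb of such a gene and was at 0 in exactly the same blocks (7 genes). Srprb on chromosome 9, which lies beside Trf, was such a neighbour. This rule was chosen after seeing the data. It removed 96 genes, 28 of them protein-coding. Of these 28, 26 failed in the Het APAP block, 24 in WT saline, 10 in OE saline, 2 in Het saline, 1 in OE APAP and 0 in WT APAP. Alb was listed at 0 in all libraries and could not be tested.

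Values were tested as log2(FPKM + 1), so fold changes are on that scale and understate the change of low genes. Genes with a mean of at least 1 FPKM over the 17 libraries were kept, which left 11101. limma 3.58.1 (with statmod 1.5.0, in R 4.3.3) fitted a mean for each of the 8 label groups and a term for liver perfusion, with a trended and robust variance prior, and p-values were adjusted by the Benjamini-Hochberg method at a false discovery rate of 0.05. The fit had 8 residual degrees of freedom. Perfusion followed the sequencing lane: libraries of lanes L007 and L008 came from perfused livers and those of lanes L004 to L006 did not, so perfusion and lane cannot be told apart. The averaged response is the mean of the APAP minus saline differences of the 3 genotype labels. The single libraries given saline by IG or APAP at 300 mg/kg were groups of their own. Nothing in the labels pairs animals across groups, but groups share lanes in part. Lane L008 holds perfused livers of both Het and both OE groups, L004 the non-perfused OE livers, and L005 the WT APAP livers and 2 Het APAP livers. WT saline was run in lanes L006 and L007, with no other group but the IG library.

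The gene lists were fixed before the data were examined, as were the design and the rule for named genes. They cover NAD metabolism, drug metabolism, stress and inflammation, lipid, bile acid and energy metabolism, the clock, sex-biased genes and markers of liver cell types. The 28 lists with at least 5 measured genes, of all those fixed, were tested with limma's camera at a preset correlation of 0.01 between genes. Each was also tested with a correlation estimated from the data and with fry, whose p tests whether the genes of a list move on balance in one direction, without comparing them with other genes. Lists overlap in part, so their results are not independent.

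The genes named in a comparison are Nampt, and up to 10 higher and 10 lower genes with the largest change among those that passed, with at least 5 FPKM in the higher group and no overlap between the libraries of the groups. For the averaged response the sign had to be the same in all 3 genotypes. Predicted genes, small RNAs and pseudogenes were left out of that ranking. Named as well are up to 4 members of each list with the smallest p, 12 sentinel genes in the APAP comparisons, and, where 5 or fewer genes passed, all of them, or the 5 with the smallest p where none did. Some genes that this rule selects are not reported here. Members of multigene families (Mup17, Saa1 and Saa2, Hba-a1, Cyp4a10 and Cyp4a14, the Cyp2d and the Ugt2b genes) can share reads with close copies and are uncertain. Gene positions are from a GENCODE annotation of GRCm38.

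Alternatives tried were no perfusion term, the rare labels pooled with their nearest group, a pseudocount of 0.1, no filter and a filter at a mean of 5, median-of-ratios scaling, quantile normalisation, array weights, a change of at least 2-fold required as well, perfused libraries alone, non-perfused libraries alone with the rare labels pooled, the compared groups alone, and each library left out in turn. Failed estimates kept, their neighbours kept, a fit with lane in place of perfusion, for the 4 comparisons whose groups are linked by shared lanes, and a fit without a pair of libraries that stood apart were added after seeing the data. A count-based test (DESeq2) was planned for count data and was not run, since no counts were used. Neither scaling moved the median change of all genes by as much as 0.1 on the log2 scale.

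The procedure was tested on simulated data with 100 genes changed at each size among 11101. The simulated noise was normal, independent between genes and of the same spread in every library. Outlying libraries and genes that move together are thus not covered, and the shares may overstate the recovery in the real livers. Between 2 and 16 unchanged genes were called per comparison. At a log2 change of 2, it recovered 95% for the averaged response, 88% for the response in WT, 95% in Het and 87% in OE. At the same size it recovered 93% and 86% for Het and OE against WT under saline and 96% and 92% under APAP. It recovered 76% for each of the differences of response and 95% for perfusion. At a log2 change of 1 the shares were 87% for the averaged response, 56%, 53% and 48% for the responses in WT, Het and OE, and 51%, 59%, 61% and 53% for Het and OE under saline and Het and OE under APAP. They were 38% and 23% for the differences of response of Het and OE, and 91% for perfusion.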

Results

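Gene expression was measured in 17 livers of male C57BL/6 mice, a common inbred strain, 24 h after an injection of acetaminophen (APAP) or saline. APAP is a painkiller that the liver clears by glucuronidation and sulfation, and at high dose cytochrome P450s such as Cyp2e1 turn part of it into a reactive product that injures hepatocytes around the central vein. The mice carried 3 genotype labels at Nampt, the gene of the rate-limiting enzyme that makes NAD from nicotinamide: +/+ (called WT here), +/- (Het) and OE, which the labels do not spell out. The study's title asks about a protective role of Nampt in this injury. Saline was given to 3 WT, 2 Het and 2 OE mice and APAP at 200 mg/kg to 3 WT, 3 Het and 2 OE mice. Another WT mouse had saline labelled IG and another OE mouse had APAP at 300 mg/kg, each alone in its group. Replicates are numbered by the order in which they were deposited, so a number is only a name.

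Values are FPKM per gene, the sequencing depth behind them is unknown, and 11101 genes were tested with limma on log2(FPKM + 1). Errors of log2 fold changes are standard errors and errors of FPKM are SDs. The livers of 2 of 3 WT saline, both Het saline, 1 of 2 OE saline, 0 of 3 WT APAP, 1 of 3 Het APAP and 1 of 2 OE APAP mice had been perfused. Every fold change is adjusted for perfusion, which followed the sequencing lane. WT saline livers shared no lane with any other group but the IG library, so the WT response and the saline differences from WT cannot be told apart from lane, within perfused or non-perfused livers too. The averaged response and the differences of response include the WT response. OE and WT APAP livers shared no lane either and are linked only through Het livers. WT saline 1 and 2, OE APAP 2 and the 300 mg/kg mouse were 12 weeks old and the others 11. The first principal component held 41.8% of the variance. WT and Het saline libraries scored between -31.1 and -26.1 on it, OE saline -15.8 and -22.2, WT APAP 6.36, 13.7 and 38.7, Het APAP 38.2, 63.5 and 56.5, and OE APAP -12.2 and 9.13. The second component (12.7%) set OE saline 2 (38.9) and OE APAP 1 (39.0) apart from every other library, the next highest being Het saline 2 at 15.5.

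Nampt mRNA (ENSMUSG00000020572, chromosome 12, 32819545 to 32853349 on the plus strand of GRCm38) was not lower in the livers labelled Het than in those labelled WT. Under saline it stood at 17.1 ± 1.54 FPKM in WT (n = 3), 24.5 ± 2.10 in Het (n = 2) and 24.8 ± 3.42 in OE (n = 2), and the IG library had 23.4. After APAP it stood at 13.2 ± 3.12 in WT (n = 3), 13.9 ± 2.29 in Het (n = 3) and 27.2 ± 12.3 in OE (n = 2, 36.0 and 18.5), and the 300 mg/kg library had 18.2. The Het minus WT difference was 0.57 ± 0.25 under saline (95% interval 0.04 to 1.11, limma adjusted p = 0.397) and 0.16 ± 0.22 under APAP (-0.33 to 0.64, adjusted p = 0.736). Within perfused saline livers it was 0.53, and within lane L005 after APAP it was 0.01. The OE minus WT difference was 0.47 ± 0.24 under saline (adjusted p = 0.902; 0.41 within perfused livers) and 1.05 ± 0.26 under APAP (0.50 to 1.61, adjusted p = 0.122; 1.40 within non-perfused livers). The last value was 0.43 with lane in place of perfusion, 0.51 without OE APAP 1 and 1.40, then past the threshold, without OE APAP 2. With array weights the Het minus WT difference under saline was 0.46 and passed. Nampt mRNA did not follow the Het label. A rise with the OE label was not established either, since neither OE minus WT difference passed in the main fit. The OE saline livers (22.4 and 27.2 FPKM) stood near the Het saline livers and the IG library, and OE APAP 1 weighed on the difference under APAP. WT, Het and OE stand below for libraries labelled so.

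**Figure D1:**
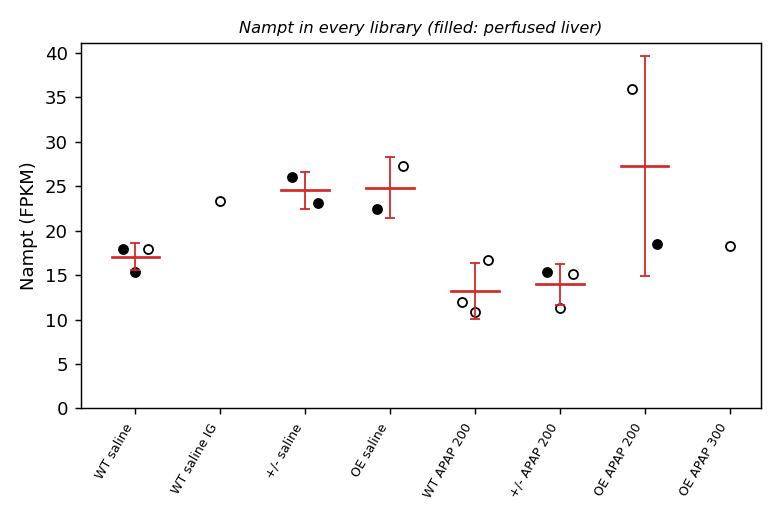
Nampt FPKM (vertical axis) in each of the 17 livers by label group (horizontal axis), filled points being perfused livers and red marks the group mean ± SD. Het saline livers had 23.0 and 26.0 FPKM against 15.3 to 18.0 in the WT saline livers, and OE APAP livers had 36.0 and 18.5.

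Averaged over the genotype labels, APAP raised acute phase genes and 2 metallothioneins and lowered genes of pericentral hepatocytes, of drug metabolism, of bile acid metabolism and of fatty acid oxidation (8 APAP and 7 saline livers). Saa2 and Saa1, serum amyloid proteins made in the acute phase, rose by 6.83 ± 1.19 and 6.01 ± 0.94 on the log2 scale (adjusted p = 0.00484 and 0.00285). The metallothioneins Mt2 and Mt1 rose by 6.75 ± 0.97 and 5.37 ± 0.56 (adjusted p = 0.00223 and 4.87e-04), and Lcn2, an iron-siderophore binding protein, by 6.06 ± 1.07. Glul, glutamine synthetase of the hepatocytes next to the central vein, fell by 3.39 ± 0.25 (adjusted p = 5.41e-05), from 350 ± 27.2 to 26.9 ± 11.4 FPKM in WT and 433 ± 46.8 to 18.2 ± 3.49 in Het. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, fell by 3.08 ± 0.48, and Slc1a2, a glutamate transporter, by 3.06 ± 0.40. Among the 10 strongest rises were also Orm2 (4.14), S100a9 (3.58), Gsta1 (3.55), S100a8 (3.53) and Saa3 (3.40). The 10 strongest falls included Mup17 (-4.12), Hsd3b5 (-2.87), Acaa1b (-2.84), Sult2a8 (-2.81), Cyp2c37 (-2.73), Cyp4a14 (-2.62) and Inmt (-2.61).

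Of 22 measured acute phase genes, 18 rose and 4 did not pass (18 also when adjusted over the list alone, median 1.64), among them Apcs (2.89), Fgg, a fibrinogen chain (1.68), and Itih3 (0.90). The list was higher by camera (adjusted p = 8.91e-14; adjusted p = 0.192 with an estimated correlation). Markers of monocytes and infiltrating macrophages rose in 9 of 15 and 6 did not pass (11 adjusted over the list alone, camera adjusted p = 2.54e-07; adjusted p = 0.226 with an estimated correlation). Chil3 rose by 2.57, Lgals3 by 2.04 and Cd68, a lysosomal protein of macrophages, by 1.33. Of 4 measured neutrophil markers S100a8, S100a9 and Csf3r rose, too few genes for a list test. Of 13 cytokine and chemokine genes 8 rose (9 adjusted over the list alone, camera adjusted p = 2.12e-06; adjusted p = 0.201 with an estimated correlation). These included the monocyte attractants Ccl2 (2.83) and Ccl7 (2.26), the neutrophil attractant Cxcl1 (2.64) and the signalling inhibitor Socs3 (2.18). Matrix and stellate cell genes rose in 11 of 17 and fell in 3 (12 and 3 adjusted over the list alone, camera adjusted p = 6.21e-05; adjusted p = 0.226 with an estimated correlation). Timp1, an inhibitor of matrix proteases, rose by 2.09, Tagln by 1.86 and Col4a1 by 1.65. None of the 28 lists tested in any comparison held its camera call with an estimated correlation. By fry 18 lists moved in the averaged response, 16 of them also called by camera.

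Stress genes rose in part. Cdkn1a, the p53 target that halts the cell cycle, rose by 2.11 ± 0.26 (adjusted p = 5.14e-04), from 0.161 ± 0.179 to 5.39 ± 2.44 FPKM in WT and from 0.294 to 13.4 ± 6.74 in Het. Of 13 p53 targets 5 rose (6 adjusted over the list alone, camera adjusted p = 8.67e-04; adjusted p = 0.192 with an estimated correlation). Among them were Btg2 at 1.56, Trp53inp1 at 1.15 and the cell death gene Bax at 0.60. Of 20 genes of the integrated and endoplasmic reticulum stress responses 7 rose (8 adjusted over the list alone, camera adjusted p = 2.95e-04; adjusted p = 0.192 with an estimated correlation). The transcription factor Atf3 rose by 2.28, Sdf2l1 by 1.08 and Trib3 by 0.91. The cell cycle list had 5 of 13 higher (7 adjusted over the list alone, camera adjusted p = 0.00149; adjusted p = 0.215 with an estimated correlation). The DNA replication genes Mcm6 and Mcm2 rose by 0.83 and 0.67 and the cyclin Ccne1 by 0.66. Cyclin Ccnd1 had 0.15 (adjusted p = 0.55). Among 23 targets of the antioxidant regulator Nrf2, 7 rose and 3 fell and the list was not called (7 and 3 adjusted over the list alone, adjusted p = 0.0634). Hmox1, which degrades haem, rose by 1.51 ± 0.35, and Abcc4, Cbr3 and Srxn1 rose by 1.12, 1.01 and 0.98, while Nqo1 (0.17, adjusted p = 0.709) and Gclc (-0.05, adjusted p = 0.863) did not pass. Gdf15, a secreted stress protein, had 0.39 (adjusted p = 0.267).

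Metabolic genes fell across several lists. Of 24 genes of fatty acid oxidation and Ppara targets 21 fell and 1 rose (the same counts adjusted over the list alone, camera adjusted p = 1.43e-10; adjusted p = 0.192 with an estimated correlation). The thioesterase Acot1 fell by 2.36 and Creb3l3 by 0.75. Genes of APAP conjugation fell in 18 of 21 and 1 rose (19 and 1 adjusted over the list alone, camera adjusted p = 3e-10; adjusted p = 0.192 with an estimated correlation). They included the glucuronosyltransferases Ugt2b1 (-1.72) and Ugt3a2 (-1.22) and the sulfotransferase Sult5a1 (-1.31). Of 20 xenobiotic P450 genes 17 fell (17 adjusted over the list alone, camera adjusted p = 7.51e-08; adjusted p = 0.215 with an estimated correlation). Cyp2e1 fell by 2.56 ± 0.49, from 2082 ± 135 to 493 ± 296 FPKM in WT, and Cyp2d9 and Cyp2f2 fell by 2.10 and 1.10. Of 16 bile acid genes 13 fell (14 adjusted over the list alone, camera adjusted p = 2.3e-08; adjusted p = 0.192 with an estimated correlation). The synthesis enzyme Cyp8b1 fell by 2.41, the uptake transporters Slco1b2 and Slc10a1 by 2.11 and 1.89, and the bile acid receptor Nr1h4 by 1.09. Of 14 pericentral hepatocyte markers 10 fell (13 adjusted over the list alone, camera adjusted p = 7.51e-08; adjusted p = 0.192 with an estimated correlation), among them Oat (-2.19) and Rhbg (-1.52). Of 15 periportal markers 6 fell and 1 rose without a list call (camera adjusted p = 0.13).

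NAD genes were part of that fall. Of 20 measured genes of NAD synthesis and salvage 13 fell, 1 rose and 6 did not pass (16 and 2 adjusted over the list alone, camera adjusted p = 4.22e-06; adjusted p = 0.192 with an estimated correlation). Afmid, of the route from tryptophan, fell by 1.78 ± 0.29, Nmrk1, which phosphorylates nicotinamide riboside, by 1.15 ± 0.15, and Naprt, which uses nicotinic acid, by 0.68 ± 0.12, while Nampt itself had -0.46 ± 0.16 (adjusted p = 0.0544). Of 15 NAD-consuming enzymes 4 fell and 1 rose, with the sirtuins Sirt3 at -0.67 and Sirt7 at -0.47, and the list was not called (adjusted p = 0.613, median 0.05 but mean -0.10). Mitochondrial respiration genes fell in 12 of 19 (13 adjusted over the list alone, camera adjusted p = 1.06e-05; adjusted p = 0.217 with an estimated correlation), such as Ndufs1 (-0.73) and Uqcrc1 (-0.56). Male-biased liver genes fell in 9 of 17 (12 adjusted over the list alone, camera adjusted p = 5.07e-06; adjusted p = 0.192 with an estimated correlation), with Cyp4a12a at -1.60 and Nudt7, a peroxisomal hydrolase, at -1.55. Of 16 gluconeogenesis and urea cycle genes 7 fell and 1 rose (adjusted p = 0.0297; adjusted p = 0.326 with an estimated correlation), led by Asl (-1.56) and Slc25a13 (-1.14). Of 15 lipogenesis genes 4 fell (adjusted p = 0.03; adjusted p = 0.577 with an estimated correlation). Kupffer cell markers fell in 2 of 14, endothelial ones rose in 1 and fell in 1 of 14, cholangiocyte ones rose in 1 and fell in 1 of 5, and erythroid ones fell in 1 of 7. None of these lists was called (camera adjusted p = 0.599, 0.88, 0.797 and 0.776), and the cholangiocyte list had a median of -0.09 though its camera test pointed up. The 20 interferon and 21 cholesterol synthesis genes did not pass singly, and neither list was called (adjusted p = 0.613, median -0.07 but mean 0.05, and adjusted p = 0.337).

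In this averaged comparison 2561 genes passed, 1087 higher and 1474 lower, and 520 of them changed at least 2-fold. Quantile normalisation gave 1150 higher and 1162 lower, and 1940 of the 2561 passed again. The count was 873 without OE APAP 2, 1290 without OE saline 2, and 1634 without OE saline 2 and OE APAP 1, the pair apart on the second component, in which 1471 of the 2561 passed again.

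**Figure D2:**
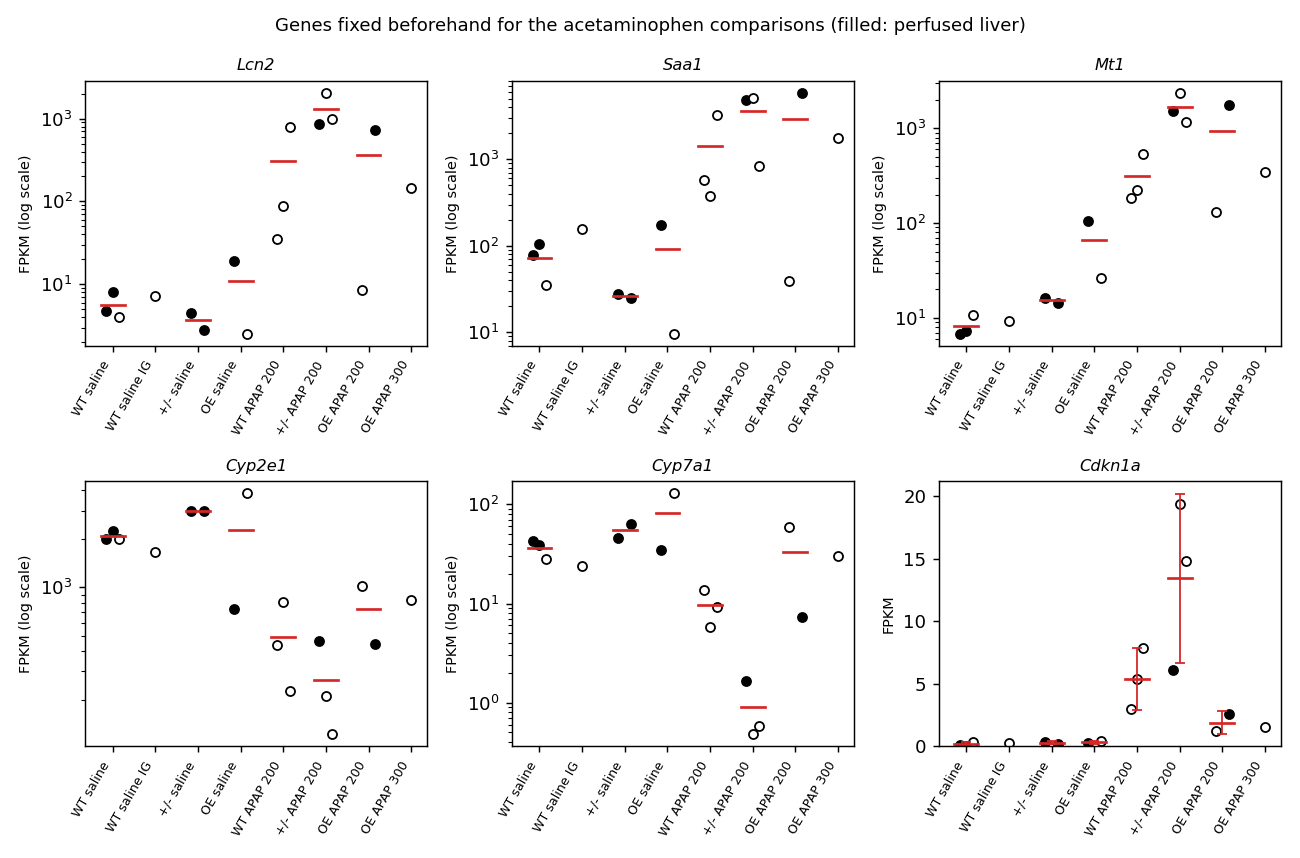
FPKM of Lcn2, Saa1, Mt1, Cyp2e1 and Cyp7a1 (log axes) and Cdkn1a (linear axis, with mean ± SD) in each liver by label group, filled points being perfused livers. In WT livers Mt1 went from 8.25 ± 2.16 to 316 ± 194 FPKM, while OE APAP 1 and 2 had 8.57 and 725 FPKM of Lcn2.

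In livers labelled WT, Mt2 and Mt1 rose by 7.13 ± 1.49 and 5.64 ± 0.87 (3 APAP and 3 saline livers, the first at an adjusted p of 0.0302). Nupr1, a stress-induced chromatin protein, rose by 2.93 ± 0.29 (adjusted p = 7.39e-04), Gsta1, a glutathione transferase, by 3.84 ± 0.61 and Ccl2 by 2.78 ± 0.67, from 1.02 to 14.0 ± 9.57 FPKM. Glul fell by 3.95 ± 0.39 (adjusted p = 7.39e-04), Slc1a2 by 2.94 ± 0.61 and Prodh, a proline-degrading enzyme, by 2.41 ± 0.29. Further strong rises were those of Orm2 (4.57), Prtn3 (3.22), Apcs (2.93), Dnajc12 (2.70) and S100a4 (2.56), and further strong falls those of Mup17 (-6.03), Rgs16 (-2.80), Acaa1b (-2.70), Sult2a8 (-2.65), Acss3 (-2.44), Nrep (-2.43) and Sucnr1 (-2.41). Cdkn1a (2.15, adjusted p = 0.0139), Atf3 (2.41) and the asparagine synthetase Asns (1.99, adjusted p = 0.0391) rose too. Lcn2 (5.64, adjusted p = 0.0814), Saa1 (5.82, adjusted p = 0.0519), Cyp2e1 (-2.46, adjusted p = 0.0803), Cyp7a1 (-2.30) and Hmox1 (adjusted p = 0.303) did not pass. Lcn2 stood at 34.8, 88.4 and 800 FPKM in the 3 WT APAP livers, the last being replicate 3.

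By list, 8 of 22 acute phase genes rose in WT (15 adjusted over the list alone, camera adjusted p = 3.04e-12) and 2 of 15 monocyte markers (6 adjusted over the list alone, camera adjusted p = 1.68e-06). With an estimated correlation the adjusted p was 0.233 and 0.259. Of 20 stress response genes 3 rose (6 adjusted over the list alone, camera adjusted p = 7.02e-06; adjusted p = 0.233 with an estimated correlation). Of 23 Nrf2 targets 6 rose and 1 fell (7 and 1 adjusted over the list alone, camera adjusted p = 0.0131; adjusted p = 0.272 with an estimated correlation). Those Nrf2 targets included Abcc4 (1.79) and Srxn1 (1.48), and the list median of 0.17 became -0.01 with rare labels pooled and -0.02 without WT APAP 2. Conjugation genes fell in 11 of 21 (17 adjusted over the list alone, camera adjusted p = 3.72e-10) and fatty acid oxidation genes in 6 of 24 (17 adjusted over the list alone, camera adjusted p = 7.75e-09). Both lists had an adjusted p = 0.233 with an estimated correlation. Bile acid genes fell in 8 of 16 (11 adjusted over the list alone, camera adjusted p = 3.16e-07; adjusted p = 0.233 with an estimated correlation). Of 20 NAD synthesis genes Nmrk1 (-1.19) and Kmo (-0.89) fell (10 lower and 1 higher adjusted over the list alone, camera adjusted p = 2.21e-05; adjusted p = 0.233 with an estimated correlation). Camera called 19 lists and fry 14. Within non-perfused livers, with the IG library counted as saline (3 against 2), Glul had -3.81, Mt1 4.69, Lcn2 4.41, Saa1 3.57 and Cyp7a1 -1.42. The list medians there were 1.16 for acute phase, -1.03 for conjugation, -0.65 for fatty acid oxidation and 0.83 for monocyte markers. The cholesterol synthesis list had a median of 0.61 (0 of 21 passed, adjusted p = 0.00353; adjusted p = 0.581 with an estimated correlation) but -0.15 within non-perfused livers, -0.14 in the 6 libraries alone and -0.06 with no perfusion term.

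In WT 611 genes passed, 217 higher and 394 lower (235 and 246 with quantile normalisation), 329 of them by at least 2-fold. This count rested on single libraries: it was 138, 223 and 346 without WT saline 3, 1 and 2, 242 without WT APAP 3 and 964 without Het APAP 1. It was 1237 with no perfusion term, 403 without the pair apart on the second component, 156 among non-perfused livers with IG counted as saline, 170 without a filter on low genes, and 13 from the 6 libraries alone.

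In livers labelled Het (3 APAP and 2 saline livers), Saa2 rose by 9.80 ± 1.99 and Mt2 by 9.49 ± 1.63. Lcn2 rose by 9.25 ± 1.79 (adjusted p = 0.00862, from 3.66 ± 1.23 to 1295 ± 644 FPKM) and Saa1 by 8.72 ± 1.59 (adjusted p = 0.00602). Mt1 rose by 7.32 ± 0.95, from 15.3 ± 1.44 to 1687 ± 606 FPKM. Slc1a2 fell by 5.36 ± 0.67 (adjusted p = 0.00124), Cyp7a1 by 5.33 ± 0.81, from 55.0 ± 13.0 to 0.907 ± 0.659 FPKM, and Glul by 4.73 ± 0.42 (adjusted p = 2.11e-04). Other strong rises were those of Orm2 (6.39), S100a9 (6.10), S100a8 (5.45) and Gsta1 (5.02), and other strong falls those of Cyp4a10 (-5.11), Cyp4a14 (-4.99), Hsd3b5 (-4.88), Ehhadh (-4.76), Acaa1b (-4.54), Sult2a8 (-4.48) and Acot1 (-4.12). Cdkn1a (3.10), Hmox1 (2.91, adjusted p = 0.00703), Atf3 (3.47) and the heat shock protein Hspa1a (2.61) rose, and Cyp2e1 fell by 3.91 (adjusted p = 0.00834). Nampt fell by 0.93 ± 0.27 (adjusted p = 0.0269), a difference of -0.64 within perfused livers.

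Of 22 acute phase genes 15 rose in Het (18 adjusted over the list alone, camera adjusted p = 4.01e-11; adjusted p = 0.207 with an estimated correlation). Of 15 monocyte markers 10 rose (11 adjusted over the list alone, camera adjusted p = 1.31e-07; adjusted p = 0.215 with an estimated correlation), including Chil3 (4.18). Of 17 matrix genes 11 rose (13 higher and 3 lower adjusted over the list alone, camera adjusted p = 1.03e-05; adjusted p = 0.207 with an estimated correlation), including Timp1 (3.70). Of 24 fatty acid oxidation genes 21 fell and 1 rose (the same adjusted over the list alone, adjusted p = 5.09e-11; adjusted p = 0.207 with an estimated correlation). Conjugation genes fell in 18 of 21 (18 adjusted over the list alone, camera adjusted p = 2.13e-10) and P450 genes in 16 of 20 (17 adjusted over the list alone, camera adjusted p = 6.46e-08). Both lists had an adjusted p = 0.207 with an estimated correlation. Of 20 NAD synthesis genes 14 fell and 1 rose (the same adjusted over the list alone, camera adjusted p = 1.08e-06; adjusted p = 0.207 with an estimated correlation). Those that fell included Afmid (-3.07), Nmrk1 (-1.95), Naprt (-1.39) and Nadk (-1.02). Haemoglobin Hbb-bs, a red blood cell gene, stood at 26.7, 973 and 341 FPKM in Het APAP 1, 2 and 3 and at 20.9 and 8.37 in the Het saline livers, of which only Het APAP 2 and 3 were not perfused. Within perfused livers the erythroid list had a median of 0.45. The platelet gene Pf4 rose by 2.47 (adjusted p = 0.0436), a difference of 1.36 within perfused livers. Within perfused livers (1 against 2) Lcn2 had 7.54, Saa1 7.44, Mt1 6.55, Glul -4.23 and Cyp7a1 -4.37. The list medians there were 2.15 for acute phase, -1.72 for fatty acid oxidation, -1.25 for conjugation, 1.62 for monocyte markers and -0.89 for NAD synthesis. In Het 2455 genes passed, 1003 higher and 1452 lower, 1261 of them by at least 2-fold. The count was 884 and 898 without Het saline 1 and 2, which leaves a lone saline library assumed to vary like the other groups, 824 from the 5 libraries alone, and 838 with lane in place of perfusion. Of the genes that passed in WT, 179 higher and 349 lower ones passed in Het too, against 19.6 and 51.5 for independent lists. Both responses come from 1 fit and share its gene variances and perfusion term, so their overlap can exceed independence by construction.

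In livers labelled OE no single gene passed (2 APAP and 2 saline livers). The smallest p-values were those of Psat1, a serine synthesis enzyme (1.41 ± 0.23), Arrdc3 (-3.04 ± 0.47) and the peptidase Mme (-1.13 ± 0.19), each at an adjusted p of 0.201. Slc41a2 (1.65 ± 0.29) and Fitm1 (-1.80 ± 0.33) followed. Psat1 stood at 0.684 FPKM under saline and 3.40 after APAP. Lcn2 had 3.31 ± 1.77 (adjusted p = 1), Saa1 3.50 ± 1.57, Mt1 3.15 ± 0.94 (adjusted p = 0.932), Glul -1.49 ± 0.42 (adjusted p = 0.923), Cdkn1a 1.09 ± 0.43 and Nampt 0.06. The 2 APAP livers stood far apart, with Lcn2 at 8.57 and 725 FPKM, Saa1 at 39.5 and 5808, and Cyp7a1 at 58.7 and 7.27 in replicates 1 and 2. Camera still called 12 lists, 5 without OE APAP 2, and fry none. Acute phase genes had a median of 1.07 (camera adjusted p = 1.65e-13) and pericentral markers -0.86, with 2 lower when adjusted over the list alone (camera adjusted p = 6.67e-08). Both lists had an adjusted p = 0.412 with an estimated correlation. Bile acid genes had -0.48 (camera adjusted p = 1.72e-05) and cytokines 0.77 (camera adjusted p = 2.36e-05). With an estimated correlation the adjusted p was 0.412 and 0.439. In the perfused pair Lcn2 differed by 5.17, Saa1 by 5.06, Mt1 by 4.04 and Glul by -0.84. In the non-perfused pair, OE APAP 1 and OE saline 2, the differences were 1.45, 1.93, 2.27 and -2.13. The acute phase medians of these pairs were 1.94 and 0.31. limma called 0 genes, with 533 at an unadjusted p below 0.05, and no second tool was run on single genes. The count was 12 without OE APAP 1, 1 without OE APAP 2, 1 without OE saline 1 and 108 among perfused livers.

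**Figure D3:**
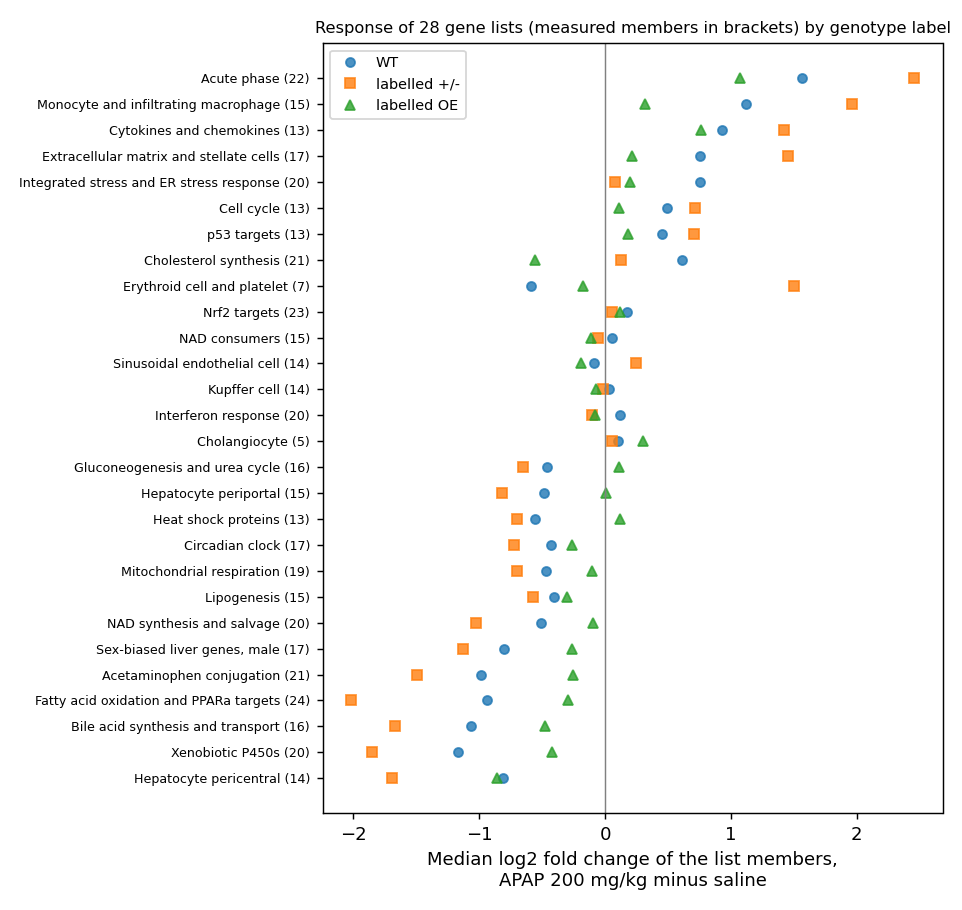
Median log2 fold change after APAP (horizontal axis) of each of the 28 tested gene lists (vertical axis), with a marker for each genotype label. For the acute phase list the medians were 1.56 in WT, 2.46 in Het and 1.07 in OE, and for fatty acid oxidation -0.94, -2.02 and -0.30.

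Whether the response differed between genotype labels was tested on the difference of responses. Over the 1087 genes that rose on average the median response was 0.66 in WT, 0.97 in Het and 0.29 in OE, and over the 1474 that fell it was -0.66, -0.95 and -0.24. The Het value lay beyond the WT value in 880 and 1241 of these genes, and the OE value fell short of the WT value in 953 and 1357. These genes were chosen on the mean of the same responses and are not independent, so the counts only describe them. OE APAP 1, which stood apart on the second component, weighs on the OE values. No single gene passed: limma called 0 for Het minus WT, with 916 at an unadjusted p below 0.05 and a smallest adjusted p of 0.225, and 0 for OE minus WT, with 664 and 0.418. The smallest p-values belonged to Itpr2, a calcium channel of the endoplasmic reticulum (-1.26 ± 0.19), Rfx5 (-1.24 ± 0.20), Fam129b (1.98 ± 0.34), E2f8 (-1.40 ± 0.27) and the oestrogen receptor Esr1 (-1.51 ± 0.29) for Het. For OE they belonged to Pmm1 (-1.60 ± 0.29), Sgf29 (1.12 ± 0.21), Errfi1 (1.96 ± 0.38), Ica1 (-1.32 ± 0.26) and the export pump Abcc4 (-1.36 ± 0.27). Mt1 and Cyp7a1 differed by 1.68 ± 1.15 and -3.03 ± 0.99 between Het and WT. The count for Het rose to 427 with array weights, 30 with failed estimates kept, 4 with no filter and 2 with the neighbours of failed estimates kept. For OE it was 9 with failed estimates kept and 4 among non-perfused livers with IG and 300 mg/kg pooled. For Het 2 genes passed without Het APAP 3 or WT APAP 3 and 1 without Het APAP 2, and for OE 1 passed without OE APAP 1, OE APAP 2 or OE saline 1.

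Under saline 4 genes passed between Het and WT livers (2 against 3). Gm6472, a transcribed processed pseudogene (X, 152909505 to 152910155), was higher by 2.68 ± 0.27 (16.1 ± 3.62 against 1.76 ± 0.539 FPKM, adjusted p = 0.00381), and the hydrolase gene Abhd2 (chromosome 7, 79273199 to 79365508) by 1.51 ± 0.20 (36.8 ± 1.97 against 13.6 ± 2.12). Slc22a7, an organic anion transporter (chromosome 17, 46432183 to 46438457), had -1.64 ± 0.22 (5.48 ± 1.31 against 17.1 ± 1.64), and Cnmd, chondromodulin (chromosome 14, 79637690 to 79662170), had -1.57 ± 0.21, each at an adjusted p of 0.0226. Reads of a processed pseudogene can be shared with its parent gene, so the Gm6472 value is uncertain. Of 15 lipogenesis genes none passed over all genes but 11 were lower adjusted over the list alone, with Acss2 at -2.81, Acacb at -2.54 and Acly at -2.12 (camera adjusted p = 5.8e-10; adjusted p = 0.902 with an estimated correlation). Of 24 fatty acid oxidation genes 13 were higher adjusted over the list alone, with Cyp4a10 at 3.29, Cyp4a31 at 2.75 and Acot1 at 2.25 (camera adjusted p = 5.8e-10; adjusted p = 0.902 with an estimated correlation). Of 20 interferon genes 2 were higher adjusted over the list alone, with Ifit1 at 1.81 and Usp18 at 1.41 (camera adjusted p = 1.29e-07; adjusted p = 0.902 with an estimated correlation). The erythroid list had a median of -1.01 (camera adjusted p = 0.0325; adjusted p = 0.902 with an estimated correlation). Also called were heat shock (median 0.66), cholesterol synthesis (-0.45) and the cell cycle (-0.27). On the second component the Het saline livers scored 9.73 and 15.5 and the WT saline livers -13.7, -9.27 and -13.3. Of the called lists, all but interferon and erythroid genes moved as in the pair apart on that component, set against its group partners. Within perfused livers Gm6472 had 2.72, Abhd2 1.49, Slc22a7 -1.48 and Cnmd -1.63. At an unadjusted p below 0.05 there were 1314 genes. Over about 30 alternatives Gm6472 lost its call in 1, Abhd2 in 9, Cnmd in 10 and Slc22a7 in 11. The count was 0 without Het saline 2, 1 without Het saline 1, WT saline 1 or WT saline 3, 2 without WT saline 2, 11 without WT APAP 3 and 1698 with array weights. Camera called 7 lists, 3 without Het saline 2 and 4 without WT saline 3.

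Under saline 4 genes also passed between OE and WT livers (2 against the same 3 WT livers, so the values are not independent of the preceding ones). Slc22a7 had -1.83 ± 0.22 (4.08 ± 2.36 against 17.1 ± 1.64 FPKM), Cnmd -1.72 ± 0.21 and Adh6-ps1, an unprocessed pseudogene of the alcohol dehydrogenases (chromosome 3, 138374121 to 138395002), -1.39 ± 0.17 (8.15 ± 0.138 against 24.0 ± 5.13), each at an adjusted p of 0.0124. Abhd2 was higher by 1.45 ± 0.20 (40.6 ± 6.43 FPKM, adjusted p = 0.0206). Slc22a7, Cnmd and Abhd2 had also passed between Het and WT livers, in the same direction and at like size. A shift in the shared WT saline livers or their lanes would give the same values, and it cannot be told apart from the genotype labels. Of 15 lipogenesis genes 7 were lower adjusted over the list alone (median -1.25, camera adjusted p = 2.8e-10; adjusted p = 0.289 with an estimated correlation). Of 17 male-biased genes 3 were lower adjusted over the list alone, among them Cyp4a12a at -1.36 and the steroid enzyme Hsd3b5 at -3.06 (camera adjusted p = 6.31e-09; adjusted p = 0.213 with an estimated correlation). Pericentral markers had a median of -0.48 with none of 14 passing adjusted over the list alone (camera adjusted p = 2.68e-04; adjusted p = 0.69 with an estimated correlation). Conjugation genes had -0.32, with 1 of 21 lower adjusted over the list alone (camera adjusted p = 0.00957; adjusted p = 0.815 with an estimated correlation). P450 genes had -0.29, with 1 of 20 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.0475; adjusted p = 0.815 with an estimated correlation), but 0.27 among non-perfused livers with IG counted as saline. The stress response list had a median of 0.55, with none passing adjusted over the list alone (camera adjusted p = 1.32e-06; adjusted p = 0.213 with an estimated correlation). Within perfused livers (1 against 2) Slc22a7 had -1.40, Cnmd -1.62 and Abhd2 1.47, and the list medians were -0.35 for lipogenesis, -0.83 for male-biased genes and -0.02 for the stress response. Without the pair apart on the second component, to which OE saline 2 belongs, they were -0.62, -0.65 and -0.06, the last not called, with -1.07 for pericentral markers, -0.59 for conjugation and -0.56 for P450s. At an unadjusted p below 0.05 there were 661 genes. Over about 30 alternatives Slc22a7 and Cnmd lost their calls in 8 each, Adh6-ps1 in 9 and Abhd2 in 12. The count was 0 without OE saline 2, WT saline 1, WT saline 3 or the pair apart on the second component, and 7 without OE saline 1 or WT APAP 1. Camera called 11 lists.

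After APAP 6 genes passed between Het and WT livers (3 against 3). Nudt7 (chromosome 8, 114133557 to 114154739) was lower, at -2.19 ± 0.27 (66.0 ± 20.7 against 258 ± 73.6 FPKM, adjusted p = 0.0134) and so was the glucuronosyltransferase Ugt2b1, at -1.71 ± 0.25 (19.6 ± 7.87 against 59.2 ± 21.3, adjusted p = 0.0319). Mlxipl, the carbohydrate-responsive transcription factor of lipogenesis, had -1.31 ± 0.18 (7.71 ± 2.63 against 17.6 ± 4.25, adjusted p = 0.0300), Tlcd2 -1.69 ± 0.25 and the aromatic amino acid decarboxylase Ddc -1.10 ± 0.16 (11.4 ± 0.728 against 25.0 ± 4.41). Gm6472 was higher by 3.46 ± 0.24 (28.2 ± 10.5 against 1.65 ± 0.403, adjusted p = 6.33e-05), a gene outside the naming rule here and chosen after its values were seen. Close to the threshold lay the NAD pathway genes Kynu (-1.16, adjusted p = 0.0561) and Aox3 (-2.38), Abcb11, the bile salt export pump (-1.82), and the urea cycle gene Otc (-1.16). Hmox1 (1.76, adjusted p = 0.0968), Atf3 (1.54), Chil3 (2.05), Cdkn1a (1.25), Mt1 (2.18), S100a8 (2.87) and Lcn2 (2.53, adjusted p = 0.394) did not pass.

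Camera called 18 lists in this comparison, 7 higher and 11 lower in Het, and fry 6. Of 15 lipogenesis genes 1 was lower, and 13 adjusted over the list alone (median -1.30, camera adjusted p = 4.33e-09; adjusted p = 0.356 with an estimated correlation). Of 21 conjugation genes 1 was lower, and 11 adjusted over the list alone (median -0.67, camera adjusted p = 8.77e-07; adjusted p = 0.356 with an estimated correlation). Adjusted over the list alone 6 of 20 P450 genes were lower, with Cyp1a2 at -2.38 (camera adjusted p = 2.5e-06; adjusted p = 0.388 with an estimated correlation). So were 8 of 16 bile acid genes (camera adjusted p = 2.48e-05; adjusted p = 0.356 with an estimated correlation) and 11 of 20 NAD synthesis genes (camera adjusted p = 1.18e-04; adjusted p = 0.359 with an estimated correlation), with Haao at -1.38. Monocyte markers had a median of 0.76 with none of 15 passing adjusted over the list alone (camera adjusted p = 2.48e-05; adjusted p = 0.417 with an estimated correlation). Acute phase genes had 0.53 (camera adjusted p = 0.00674; adjusted p = 0.535 with an estimated correlation). Heat shock genes had 0.65 with 1 higher adjusted over the list alone (camera adjusted p = 0.00679; adjusted p = 0.532 with an estimated correlation), but 0.44 and no call with lane in place of perfusion. The medians of Kupffer, endothelial and cholangiocyte markers, not called, were 0.11, -0.11 and -0.12. Within lane L005, where neither genotype was perfused (2 Het and 3 WT livers), Nudt7 had -2.15, Ugt2b1 -1.85, Mlxipl -1.33, Gm6472 3.57, Lcn2 3.38 and Mt1 2.56. The list medians there were -1.50 for lipogenesis, -0.82 for conjugation, -1.45 for P450s, -0.50 for NAD synthesis and 0.96 for monocyte markers. Of 31 alternatives Nudt7 lost its call in 5, Mlxipl in 11, Ddc in 13 and Tlcd2 and Ugt2b1 in 14 each. At an unadjusted p below 0.05 there were 2119 genes, 1 higher and 5 lower past the adjustment, and 23 and 65 with quantile normalisation. The count of 6 was 1493 with array weights, 750 with lane in place of perfusion, where all 6 passed again, 110 with failed estimates kept, 89 with a filter at a mean of 5, 70 with a pseudocount of 0.1 and 60 with no filter. It moved with single libraries too: it was 845 without WT APAP 3, 558 without Het APAP 1, 256 without WT saline 3, 12 without OE APAP 1 or 2, and 1 without Het APAP 2 or WT APAP 1. It was 2 without either Het saline, either OE saline, WT saline 1 or WT saline 2.

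After APAP 1 gene passed between OE and WT livers (2 against 3): Gpt2, the mitochondrial alanine aminotransferase (chromosome 8, 85492576 to 85527560), was higher by 1.53 ± 0.19 (196 ± 79.7 against 79.5 ± 10.7 FPKM, adjusted p = 0.0296). It had 253 and 140 FPKM in OE APAP 1 and 2, and lost its call in 18 of 31 alternatives, with adjusted p from 0.0153 to 0.507. Abcc4 (-1.31, adjusted p = 0.0553), the urea cycle gene Asl (2.58, adjusted p = 0.0942), Sult1a1 (1.41, adjusted p = 0.0942), the sterol enzymes Cyp51 (-2.24, adjusted p = 0.0995) and Idi1 (-2.50) and Glul (1.44, adjusted p = 0.143) did not pass. Of 21 cholesterol synthesis genes 16 were lower adjusted over the list alone (median -1.71, camera adjusted p = 1.92e-15; adjusted p = 0.4 with an estimated correlation). Of 24 fatty acid oxidation genes 14 were higher and 1 lower adjusted over the list alone (camera adjusted p = 6.41e-07; adjusted p = 0.4 with an estimated correlation). Of 13 cell cycle genes 7 were lower adjusted over the list alone, with Mcm2 at -1.09 and Mcm5 at -1.12 (camera adjusted p = 3.47e-06; adjusted p = 0.278 with an estimated correlation). Gluconeogenesis and urea cycle genes were higher in 8 of 16 and lower in 1 adjusted over the list alone (camera adjusted p = 5.11e-06; adjusted p = 0.278 with an estimated correlation). Heat shock genes were higher in 5 of 13 adjusted over the list alone, with Hspa8 at 2.09 and Dnaja1 at 1.99 (camera adjusted p = 1.46e-04; adjusted p = 0.442 with an estimated correlation). Monocyte markers had a median of -0.70 with none of 15 passing adjusted over the list alone (camera adjusted p = 0.00118; adjusted p = 0.515 with an estimated correlation). OE APAP 1, apart on the second component, was 1 of the 2 OE livers, and without that pair 9 rather than 17 lists were called. Without the pair the medians were -0.39 for cholesterol synthesis, 0.32 for fatty acid oxidation, 0.19 for heat shock and 0.12 for monocyte markers, the last 3 not called. The acute phase list went from a called -0.59 to a called 0.64 (0.72 without OE APAP 1 alone). With lane in place of perfusion 13 lists were called and 4 genes passed, all lower. The medians were then -1.08 for cholesterol synthesis, 0.38 for fatty acid oxidation, 0.03 for heat shock, 0.16 for monocyte markers and 0.29 for acute phase, the last 3 not called. Within non-perfused livers OE APAP 1 is the only OE liver at 200 mg/kg (1 against 3). There Gpt2 had 1.66, and the medians were -2.15 for cholesterol synthesis, 1.07 for fatty acid oxidation, 1.15 for heat shock and -1.01 for monocyte markers. The non-perfused OE liver given 300 mg/kg had -0.51, 0.58, -0.26 and -0.54 against the same WT livers. At an unadjusted p below 0.05 there were 1910 genes, and fry called 2 lists. The count was 99 without OE APAP 2, 65 without WT saline 3, 34 without WT APAP 1 and 7 without Het APAP 1. It was 0 without WT APAP 2 or 3, Het APAP 3, WT saline 1 or 2, or any of the Het or OE saline livers.

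Perfused and non-perfused livers differed in 6 genes, 1 higher and 5 lower, with 1834 genes at an unadjusted p below 0.05. Of the 7 perfused and 10 non-perfused livers, only those in groups holding both kinds inform the size of this term. These were WT saline (2 perfused and 1 not), OE saline (1 and 1), Het APAP (1 and 2) and OE APAP at 200 mg/kg (1 and 1). The kinase gene Vrk3 was higher by 0.72 ± 0.11 (adjusted p = 0.0457), and Rraga, a GTPase of nutrient sensing, and Mbd3, a chromatin protein, had -0.99 ± 0.13 and -0.68 ± 0.09 (adjusted p = 0.0288 each). The red blood cell gene Hbb-bs had -2.03 ± 0.66 (adjusted p = 0.208) and the erythroid list a median of -1.28, with 4 of 7 lower and 1 higher adjusted over the list alone (camera adjusted p = 0.0297; adjusted p = 0.616 with an estimated correlation). Kupffer cell markers were higher in 4 of 14 adjusted over the list alone (median 0.54, camera adjusted p = 4.4e-04; adjusted p = 0.527 with an estimated correlation). Cholesterol synthesis genes were higher in 12 of 21, also adjusted over the list alone (median 0.87, camera adjusted p = 6.65e-09; adjusted p = 0.527 with an estimated correlation). Both members of the pair apart on the second component were non-perfused. Without that pair the medians were 0.20 for Kupffer (camera adjusted p = 0.0547), 0.21 for cholesterol synthesis (0.0938) and -1.92 for erythroid genes (3.81e-06), and camera called 6 lists rather than 10. Perfusion and lane cannot be told apart. The count of genes was 111 without WT saline 3, 13 without WT APAP 2, 1 without Het APAP 1 or Het saline 1, and 0 without Het APAP 3, WT saline 1 or any of the OE libraries given saline or 200 mg/kg.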

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

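The tests of lower hepatocyte share, of the pair apart on the second component and of Nampt were chosen after the results were seen, and so was the naming of those patterns; the lane test and the counts over other splits of the samples were set beforehand.

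The APAP response of Het livers differed from that of WT livers in 13 gene lists by camera on the difference of responses, none of them by fry and none with an estimated correlation (adjusted p from 0.471 to 0.535). The median differences were -1.07 for fatty acid oxidation, -0.85 for P450s, -0.70 for pericentral markers, -0.68 for bile acid genes, -0.62 for male-biased genes, -0.56 for conjugation and -0.47 for NAD synthesis. Fatty acid oxidation was higher in Het under saline (0.75, called) and not called between Het and WT after APAP (-0.07, adjusted p = 0.486). The differences upward were 1.74 for erythroid markers, 0.93 for acute phase, 0.70 for monocyte markers, 0.63 for matrix genes, 0.43 for cytokines and 0.34 for p53 targets. The erythroid response was 0.45 within perfused Het livers and -0.26 within non-perfused WT livers, while the perfused share fell equally, from 2 of 2 to 1 of 3 in Het and from 2 of 3 to 0 of 3 in WT, so the perfusion term cancels in the 1.74. For OE against WT 19 lists differed, again none by fry or with an estimated correlation (adjusted p from 0.401 to 0.582). The medians were 0.77 for conjugation, 0.71 for P450s, 0.67 for bile acid genes, 0.66 for fatty acid oxidation, 0.64 for heat shock and for gluconeogenesis and urea cycle, 0.58 for periportal and 0.52 for pericentral markers, 0.51 for male-biased genes, 0.41 for mitochondrial respiration and 0.38 for NAD synthesis. They were -1.08 for cholesterol synthesis, -0.71 for monocyte markers, -0.66 for acute phase, -0.61 for matrix genes, -0.57 for the stress response, -0.37 for the cell cycle, -0.26 for interferon genes and -0.11 for Nrf2 targets. The OE count was 5 without OE APAP 1 and 10 without OE saline 1. Without the pair apart on the second component, P450s (0.49), NAD synthesis (0.19), mitochondrial respiration (0.21), bile acid genes (0.36), periportal markers (0.23) and acute phase (0.44) were not called. Fatty acid oxidation (0.38), cholesterol synthesis (-0.35), monocyte markers (-0.47), the cell cycle (-0.61), interferon (-0.41) and male-biased genes (0.96) were still called there. Of the 19 OE lists 9 changed the sign of their median under at least 1 alternative.

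The first pattern weighed is that Het and WT livers differed in 18 lists after APAP. Some of these lists were already called the same way under saline. Their medians under saline and after APAP were -1.27 and -1.30 for lipogenesis and 0.66 and 0.65 for heat shock. They were 0.74 and 0.55 for interferon and -0.45 and -0.56 for cholesterol synthesis. None of these lists was called on the difference of responses, so their values after APAP are not an effect of the drug by that test. Perfusion and lane as the whole cause are argued against, since within lane L005, with no perfused liver, all 18 of those lists kept the sign of their median, at a median of 119% of their size. For a lower share of hepatocytes, the other cell types did not rise alike: medians were 0.76 ± 0.18 for monocyte, 0.43 ± 0.16 for matrix and stellate, 0.11 ± 0.11 for Kupffer, -0.11 ± 0.22 for endothelial and -0.12 ± 0.23 for cholangiocyte markers, a gap of 0.887. That gap cannot decide, since other cell types may change on their own. Both hepatocyte lists were called lower in Het (medians -0.59 for pericentral and -0.61 for periportal markers). A lower share, from more monocytes or otherwise, would lower hepatocyte genes alike. Lipogenesis had a median of -1.30 while fatty acid oxidation was not called. Both lists already differed between Het and WT livers under saline, with medians of -1.27 and 0.75. Their contrast after APAP thus cannot decide on a lower share. A lower share, as the whole or a part of the cause, and a stronger injury in these particular mice stay open. So does the genotype, which was not tested apart from them. With 3 against 3 livers there are only 10 splits, too few to judge chance. The 6 genes of the real split stand against 477 for the split of WT APAP 1, WT APAP 2 and Het APAP 1 from the rest. That split followed the order of these livers on the first component, where WT and Het saline livers scored lower still. The scores were 6.36, 13.7 and 38.2 on that side, and 38.7, 63.5 and 56.5 for WT APAP 3 and Het APAP 2 and 3. Of the 10 splits, 2 gave at least 6.

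The second pattern is the pair OE saline 2 and OE APAP 1, which scored 38.9 and 39.0 on the second component. Lack of perfusion is argued against, since the highest of the other non-perfused livers scored 7.28. Lane L004 stays open: the third library of that lane, OE APAP 300, scored -13.8, but it is 1 library at another dose. Fasting stays open too, since the gluconeogenesis and urea cycle list differed from the group partners by -0.15 ± 0.52, a spread that decides nothing. Both livers carry the OE label, as do the 3 others that scored low, and no biological explanation but fasting was tested.

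The third pattern is that Nampt mRNA was not lower in Het livers. If mRNA followed the number of intact copies, swapped Het and WT labels would give a doubling and right labels a halving. Among the APAP livers the 95% interval of the Het minus WT difference, -0.33 to 0.64, excludes both. Swapped labels thus do not account for the pattern on that condition, but the test cannot show which labels are right. For the saline livers the interval, 0.04 to 1.11, excludes a halving and includes a doubling, so it does not argue against a swap there. Gm6472 would speak against a swap among the saline livers alone if it followed the genotype in both treatments, which was not tested. It was taken as the gene with the smallest p between Het and WT after APAP, a rule made after its saline values had been seen. The outcome was thus known when Gm6472 was chosen, so this gene does not decide on such a swap. In the saline livers it was higher in Het too, with a lower 95% bound of 2.09. A single wrong label, on the condition that mRNA follows the number of intact copies, does not account for the pattern either, and this too leaves the labels unjudged. With each library left out in turn the difference was 0.49 to 0.67 under saline and 0.01 to 0.37 after APAP, and the lowest lower bound was -0.50, above a halving. A transcript of the targeted allele that is still counted stays open, since the difference after APAP was 0.16 and a gene-level table does not show which part of the transcript the reads came from. A true lack of change in mRNA stays open as well, the genotype being untested.

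The OE liver given 300 mg/kg belonged to no group that was tested, and 5 sentinel genes stood above all 8 saline livers in it: Saa1 at 1782 FPKM (highest saline liver 173), Mt1 at 348 (106), Lcn2 at 143 (19.1), Nqo1 at 7.14 (5.53) and Cdkn1a at 1.53 (0.415). Gdf15 (1.09) lay below the lowest saline liver (1.44), and Cyp2e1, Gclc, Hmox1, Ccnd1 and Cyp7a1 lay inside the saline range. It is a single library, so the difference has no replicate check.

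Other splits of the samples bear on 3 more counts. For the averaged response, 2 of 100 splits drawn from 1200, the real one among them, called at least as many genes as the real one (2561). That share is below the 0.05 set beforehand, but a random split called more genes, so chance is less likely and not excluded. The highest other split called 3018, and it put OE saline 2 and OE APAP 1 on the same side with WT saline 3, WT APAP 1 and 2, both Het saline livers and Het APAP 3, so it followed the second component in part. Without that pair the real split called 1634. For WT, 1 of 10 splits, the real one, gave 611 genes and the highest other 1, and the splits are too few for a share below 0.05. For perfusion, 1 of 36 reassignments, the real one, gave 6 genes and the highest other 1, the smallest share that 36 can give. No gene passed for perfusion without the pair apart on the second component, so the count rests on few libraries. Lane and perfusion cannot be told apart either.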

How the results depend on the processing

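Keeping failed estimates, keeping their neighbours, lane in place of perfusion and leaving out the pair of libraries apart on the second component were chosen after seeing the data, and so was the comparison of list medians across alternatives. No Nampt difference between genotypes, and no named gene that had passed, changed direction under the alternatives run. Medians of called lists did in 56 of 4819 values, in 31 of 160 lists, and the cause was not tested. Counts of genes are given in the order of the alternatives, and the cause of a move was not tested unless the alternative's construction gives it, as with the 2-fold limit and with fewer libraries or other genes tested. Requiring 2-fold changes left 520 genes for the averaged response, 329 for WT, 1261 for Het and 2 for perfusion. Without the pair apart on the second component, the counts were 1634 for the averaged response, 403 for WT, 2 for OE, 9 for Het minus WT and 0 for OE minus WT under saline, 37 for Het minus WT under APAP, 1 for the OE difference of response and 0 for perfusion, with 9 lists for OE minus WT under APAP and 6 for perfusion. With no perfusion term there were 1237 genes for WT, 1 for Het minus WT under saline, 1 under APAP and 0 for OE minus WT under APAP, and 4 lists for Het minus WT under saline. With lane in place of perfusion there were 838 for Het, 750 for Het and 4 for OE under APAP. With rare labels pooled there were 1070 for WT, 2 for OE, 1 and 0 for Het and OE under saline, 10 and 22 for Het and OE under APAP and 35 for perfusion. With no filter there were 170 for WT, 1 for OE, 60 and 3 for Het and OE under APAP, 4 and 1 for the Het and OE differences of response and 0 for perfusion, and 23 lists for the Het difference. A filter at a mean of 5 gave 89 for Het under APAP and 15 for perfusion, and a pseudocount of 0.1 gave 2 for Het under saline and 70 under APAP. Median-of-ratios scaling gave 3 for OE under APAP and 14 for perfusion. Quantile normalisation gave 1 and 2 for Het and OE under saline, 88 and 0 for Het and OE under APAP and 16 for perfusion. Array weights gave 1698 for Het under saline, 1493 for Het and 0 for OE under APAP, 427 for the Het difference and 0 for perfusion, and Nampt for Het minus WT under saline passed at 0.46. Perfused libraries alone gave 108 for OE, 214 for Het and 176 for OE under saline. Non-perfused libraries alone, with IG and 300 mg/kg pooled with their nearest groups, gave 156 for WT, 6 for OE, 13 for Het under APAP and 4 for the OE difference. Comparisons without such livers in both groups have no value there. Keeping failed estimates gave 13 for OE, 34 and 16 for Het and OE under saline, 110 and 4 under APAP, and 30 and 9 for the Het and OE differences. Keeping their neighbours gave 11 for Het under APAP, 2 for the Het and 1 for the OE difference. The compared groups alone gave 13 for WT, 824 for Het, 231 and 0 for Het and OE under saline and 16 for OE under APAP. An estimated correlation left 0 lists in all 11 comparisons, where camera with the preset correlation called 7 to 19, and fry left 0 for OE, for Het and OE under saline, for both differences and for perfusion, 6 for Het and 2 for OE under APAP.

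The list medians that changed sign were these. Among non-perfused livers pooled in that way, cholesterol synthesis in WT went from 0.61 to -0.15 and P450s for OE under saline from -0.29 to 0.27. There the OE response had 0.03 for conjugation, -0.48 for the stress response, 0.29 for cholesterol synthesis and 0.29 for lipogenesis (reported as -0.25, 0.19, -0.56 and -0.30). OE APAP 1 minus OE saline 2, without the 300 mg/kg liver, had -0.16, -0.10, -0.73 and -0.34. Among the non-perfused livers with IG and 300 mg/kg pooled, the OE difference of response had 0.04 for Nrf2 targets, -1.14 for heat shock, 0.02 for the cell cycle, 0.04 for interferon, 0.18 for cholesterol synthesis and 0.11 for matrix genes. Among perfused livers, OE under saline had -0.02 for the stress response, -0.64 for heat shock, 0.05 for cholesterol synthesis and 0.07 for endothelial markers (0.55, 0.39, -0.61 and -0.15). Without the pair apart on the second component, OE under saline had -0.06 for the stress response and -0.60 for heat shock, the latter called. OE under APAP then had 0.64 for acute phase, called, and -0.12 for bile acid genes, 0.07 for matrix genes and 0.12 for monocyte markers (-0.59, 0.62, -0.49 and -0.70). The OE difference had 0.44 for acute phase and perfusion 0.03 for the stress response. With no perfusion term the values were -0.06 for cholesterol synthesis in WT and 0.08 for Nrf2 targets in the OE difference. With rare labels pooled they were -0.01 for Nrf2 targets in WT, -0.06 for the stress response in OE and 0.01 for Nrf2 targets in the OE difference. With lane in place of perfusion, OE under APAP had -0.18 for conjugation, 0.29 for acute phase, -0.35 for bile acid genes, 0.10 for matrix genes and 0.16 for monocyte markers, the first reported as 0.48. The compared groups alone gave -0.14 for cholesterol synthesis in WT, and a filter at a mean of 5 gave -0.01 for the stress response in Het. Leaving out 1 library accounted for the other 20, from -0.59 (heat shock, OE difference, without OE saline 1) to 0.72 (acute phase, OE under APAP, without OE APAP 1).

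Leaving out each library in turn gave 873 to 2689 genes for the averaged response, 138 to 964 for WT, 884 to 2624 for Het, 0 to 12 for OE, 0 to 11 and 0 to 7 for Het and OE under saline, 1 to 845 and 0 to 99 for Het and OE under APAP, 0 to 2 and 0 to 1 for the Het and OE differences, and 0 to 111 for perfusion. The numbers of lists ran from 16 to 18, 19 to 21, 16 to 18, 5 to 13, 3 to 9, 9 to 14, 16 to 20, 12 to 19, 10 to 19, 5 to 20 and 8 to 11 in the same order. Nampt ran from 0.49 to 0.67 and 0.41 to 0.55 for Het and OE under saline, and from 0.01 to 0.37 and 0.51 to 1.40 under APAP, the last passing without OE APAP 2. Where a group was left with 1 library, here or among perfused or non-perfused livers alone, that library was assumed to vary like the other groups. Such counts measure no spread within that group. No paired analysis was possible because the labels give no replicate numbers that groups share; the lanes that groups share were used as blocks in the fit with lane in place of perfusion, which gives no value for the other comparisons. DESeq2 was not run, since no counts were used. Depth is unknown, so how far low genes are limited by it cannot be given.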

Other observations

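All tests in this part were chosen after the results were seen, apart from the list tests, which were planned. Of 17 clock genes 8 fell and 2 rose in the averaged APAP response (9 and 3 adjusted over the list alone), and the list was not called (camera adjusted p = 0.0582). The protease gene Usp2, a rhythmic gene, fell by 1.75 ± 0.20, while the core clock gene Arntl rose by 0.94 ± 0.13, from 0.843 ± 0.134 to 3.42 ± 1.01 FPKM in WT, and the repressor Nfil3 by 1.26 ± 0.25. In Het 9 of 17 clock genes fell and 1 rose (9 and 3 adjusted over the list alone, adjusted p = 0.0278; adjusted p = 0.207 with an estimated correlation). The hour of day at which livers were taken is not in the labels used here. Of 13 heat shock genes 1 rose and 2 fell on average and the list was not called (adjusted p = 0.264), with Hspa1a, an inducible chaperone, at 1.03 and its partner Dnaja1 at -1.11. Of 4 measured female-biased liver genes 2 fell, and the 2 B and plasma cell genes and the 2 genes of mesothelium, pancreas and adipose tissue did not pass, too few for list tests. No listed T or NK cell gene was among the genes tested.

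OE saline 2 and OE APAP 1 were each set against the other library of their group, a comparison of single libraries that differ in perfusion too. Averaged over both, heat shock genes had a median difference of 2.19 ± 0.38, fatty acid oxidation genes 0.72 ± 0.33, cholesterol synthesis genes -1.80 ± 0.22, acute phase genes -1.52 ± 0.52, Kupffer cell markers -0.87 ± 0.18 and monocyte markers -0.63 ± 0.11. The cholesterol enzyme Hmgcs1 stood at 40.0 and 22.5 FPKM in these 2 livers against 195 and 153 in their partners, and Cyp4a14, a Ppara target, at 1755 and 1350 against 204 and 141. In OE APAP 1 Cdkn1a stood at 1.24 FPKM, above all 8 saline livers (at most 0.415), while its Lcn2 (8.57) lay inside their range.

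Gm6472 stood at 13.6 to 40.3 FPKM in the 5 Het livers and at 1.13 to 3.27 in the 12 others, with no overlap. It lies on chromosome X and Nampt on chromosome 12. The link to the label was seen in the data, and its origin was not tested. The IG saline library correlated with WT saline 1, 2 and 3 at 0.988, 0.975 and 0.977 across genes, and the lowest correlation among those 3 was 0.976. The OE library given 300 mg/kg reached 0.969 with a saline library and 0.962 with an APAP library. Genes are not independent replicates, so these values describe the libraries only.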
